A study of Homo sapiens with 6 samples.

How the data were processed

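Expression was measured in tamoxifen-resistant MCF7 cells on Affymetrix whole-transcript arrays, 3 arrays after 24 h with 0.2 uM JQ1 and 3 after 24 h with DMSO. Per the labels' protocols, equal amounts of total RNA were converted to labelled cDNA with the Affymetrix procedure for whole-transcript analysis, and the cells were kept in 100 nM 4-HT. The authors processed the arrays with Affymetrix Expression Console and RMA, per the submitters' processing notes, which give no versions or settings. RMA yields log2 values that are background-corrected and normalized between arrays, and the deposited values were read as log2 signal: they ran from 1.51 to 14.7 with similar medians on the 6 arrays. They were not logged or normalized again. Groups were taken from the labels, which call the arrays of each group biological replicates. The p-values of genes measure only the spread between these arrays. Those of exon usage also treat the probe sets of a gene as independent, and those of camera compare the genes of a list with other genes.

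The deposited table held 257430 rows, each an exon-level probe set. Rows were named through the supplied list of probe sets, in which 224320 (87.1%) had 1 gene symbol, 10159 had several and 22951 were not listed. Rows with several symbols or none stayed out of the gene tests and were tested apart. Values of 10865 rows were identical to those of another row on all 6 arrays. The 1-symbol rows gave 18701 genes with a median of 10 rows per gene; 1060 genes had 1 row and the highest number was 319. The value of a gene on an array was the median of its rows on the log2 scale. Where the rows of a gene differ in level and change unequally, that median can pass between rows, and its change is then not the change of any row. Symbols are those of the probe table; older and newer symbols were matched through a table of human reference genes, used for names alone, which gave a current symbol for 18601 genes. The genome build of the array design is not given in the sources used here, and no positions were used. No filter on dim genes was applied.

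JQ1 was compared with DMSO with limma 3.58.1 (lmFit and eBayes with default settings, two-sided) in R 4.3.3, with the package data.table (version 1.17.8). P-values were adjusted by the Benjamini-Hochberg method over all 18701 genes, and a gene counted as changed at an adjusted p under 0.05. The prior degrees of freedom were 3.83, and the median SD within a group was 0.141 with DMSO and 0.142 with JQ1. Errors are SD over the 3 arrays of a group for levels and the moderated SE of limma for changes. Fold changes are powers of 2 of the log2 change. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

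There were 32 gene lists with 692 entries from general knowledge of BET inhibition, estrogen signalling and this cell type, of which 659 were matched to the table, 6 of them through a synonym. They were BET and P-TEFb genes, BET inhibitor response markers, estrogen receptor and luminal factors, estrogen-induced and estrogen-repressed genes, SET domain methyltransferases, the MYC family, MYC targets, DNA replication and E2F genes, mitosis, homologous recombination and DNA repair, cyclins and CDK inhibitors of G1, p53 targets, the BCL2 family, clustered histone genes, interferon-stimulated genes, NF-kB targets, cholesterol synthesis, fatty acid synthesis, the unfolded protein and ATF4 response, lysosome and autophagy, receptor tyrosine kinases and ligands, hypoxia, epithelial genes, mesenchymal and fibroblast genes, basal and stem-like mammary genes, immune cell genes, immediate early genes, the xenobiotic and NRF2 response, cytosolic ribosomal proteins, oxidative phosphorylation and housekeeping genes. Each list was tested against the other genes with limma's camera at a preset correlation of 0.01, adjusted over the 32 lists, with camera at an estimated correlation and fry beside it. Members were also counted with p-values adjusted over the list alone. Some entries, among them BRD4, were not analysed here.

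Exon usage was tested with limma's diffSplice on 111247 rows whose mean was above the median of all rows, in the 10711 genes with at least 3 such rows. It asks whether the rows of a gene changed by different amounts. An exon-level row that differs in probe response also gives such a signal. Whether the rows of a gene shared a direction was tested, after the data were seen, from the larger of its lowest one-sided limma p-values for a rise and for a fall, times its number of rows.

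The comparison, tests, gene lists, alternatives and the rule for naming genes were set before the data were examined. Named were 14 genes of interest whatever their result (BRD4 among them), the 12 largest rises and 12 largest falls among changed genes whose groups did not overlap and whose mean was at or above the 25th percentile, without accession-like or open reading frame names, and up to 2 rises and 2 falls with the lowest adjusted p from each list. The 5 genes with the lowest p in the exon usage test were named too. Further list members were named after their values were seen: XBP1, CDK9, NSD1, WHSC1L1, EZH2, FOXA1 and GATA3. Alternatives were the mean of a gene's rows, its brightest row, the median of bright rows, filters at the 25th and 50th percentiles of signal, quantile and cyclic loess normalization of gene values, centring on housekeeping genes or on all genes, eBayes with trend and robust settings, array weights, the replicate number as a block, leaving out each array in turn, an adjusted p under 0.01, limma's treat against a fold of 1.2, and brighter rows for exon usage. A median of row-centred values was added after the data were seen.

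The procedure was tested on simulated data of the same size, with 18701 genes and 200 changed genes. It recovered 40% of the genes changed 1.5-fold and 95% of those changed 2-fold, with the right sign in 100% of recovered genes, and called 9 unchanged genes (0.0489%). The median estimated size for 2-fold changes was 0.98 on the log2 scale. The exon usage test recovered 97.4% of 77 genes with a changed row and called 62 of 10479 unchanged genes (0.592%). Those 62 were a large share of all its calls there, well above the 0.05 that the adjusted p is meant to hold. A list with a simulated shift had a camera p-value of 1.64e-48 and a list with no shift had 0.789. Simulated noise was independent between rows and 200 genes changed, against 5730 in the measured data. These rates and p-values need not carry over. The number of arrays limits the precision.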

Results

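RNA was measured on 6 whole-transcript arrays of MCF7, an estrogen receptor-positive human breast cancer cell line, in a form resistant to the antiestrogen tamoxifen. The cells were kept without phenol red, in stripped serum with 100 nM 4-HT. The treated group of 3 arrays came from cells given 0.2 uM JQ1 for 24 h, and the control group of 3 arrays from cells given the vehicle DMSO for as long. JQ1 is a small molecule that displaces BET proteins (BRD2, BRD3, BRD4 and BRDT) from acetylated chromatin. The labels call the 3 arrays of each group biological replicates. The median log2 signal of the probe sets lay between 7.49 and 7.52 on the DMSO arrays and between 7.43 and 7.47 on the JQ1 arrays. The number of arrays limits the precision of every value. Across genes, which are not independent replicates, arrays of a group correlated at 0.990 to 0.993 and arrays of different groups at 0.958 to 0.968. The first principal component separated the groups and held 71.4% of the variance.

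The comparison of JQ1 with DMSO asked how BET inhibition changed gene expression in tamoxifen-resistant cells. After 24 h of JQ1 the estrogen receptor gene ESR1 was 7.59-fold lower, at 6.94 ± 0.11 against 9.86 ± 0.12 on the log2 scale (SD, n = 3 each; limma, adjusted p = 8.33e-06). MYC, which encodes a growth-promoting transcription factor, was 10.2-fold lower, at 7.71 ± 0.14 against 11.05 ± 0.11 (SD, n = 3 each; adjusted p = 7.12e-06). Genes of DNA replication, mitosis and DNA repair fell almost without exception: 31 of 31, 30 of 31 and 18 of 20 measured members fell. All 3 lists passed camera, with adjusted p = 0.144, 0.208 and 0.315 with an estimated correlation. Of the lysosome and autophagy genes 14 of 24 rose, 1 fell and 9 did not pass (camera adjusted p = 3.73e-06; adjusted p = 0.144 with an estimated correlation). WHSC1, also called NSD2, encodes a histone methyltransferase and was 1.86-fold lower (fell by 0.90 ± 0.10 on the log2 scale, SE; adjusted p = 4.25e-04).

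**Figure D1:**
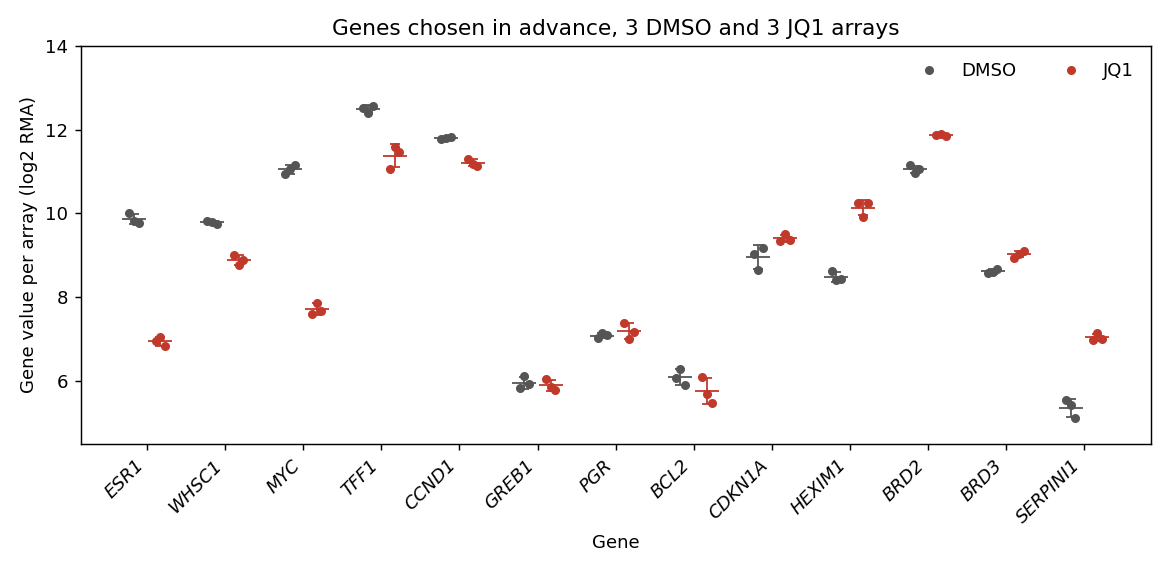
Log2 signal of 13 genes chosen before the data were examined (vertical axis) on each of the 3 DMSO and 3 JQ1 arrays (points), with the mean and SD of each group as bars. ESR1 fell from 9.86 to 6.94 and MYC from 11.05 to 7.71, whereas HEXIM1 rose from 8.48 to 10.14 and GREB1 was at 5.95 with DMSO and 5.89 with JQ1.

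Of 18701 genes tested, 5730 (30.6%) changed at an adjusted p under 0.05, of which 2384 rose and 3346 fell. That balance turned to rises in 4 other settings: 3189 rose and 3010 fell after quantile normalization of the gene values, 3973 and 2778 with arrays centred on all genes, 3046 and 2770 with the brightest probe set of each gene, and 3492 and 3352 with the median of bright probe sets. Of those changed at least 1.5-fold, 1011 rose and 2265 fell, so that 69.1% were falls. Larger changes as deposited were mostly falls: 998 genes fell and 233 rose by 2-fold, and 112 fell and 15 rose by 4-fold. The 3 JQ1 values lay wholly above or below the 3 DMSO values in 8528 genes (45.6%), where chance gives 10%. The median log2 change of all genes was 0.06. That median moved to -0.30 when arrays were centred on 17 housekeeping genes and to 0.16 when they were centred on all genes. Each centring subtracted the median level of the set on each array, which can pass between genes. The 17 housekeeping genes themselves had a median log2 change of 0.04 and a mean of 0.05. Values under that centring are therefore not changes relative to these genes, and centring on all genes pushed the median change further up. The split of the 1.5-fold changes moved with the scaling: falls made up 94.2% (287 rose, 4676 fell) after centring on housekeeping genes, 53.1% (1612 rose, 1828 fell) after centring on all genes and 59.0% (1352 rose, 1948 fell) after quantile normalization of the gene values.

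**Figure D2:**
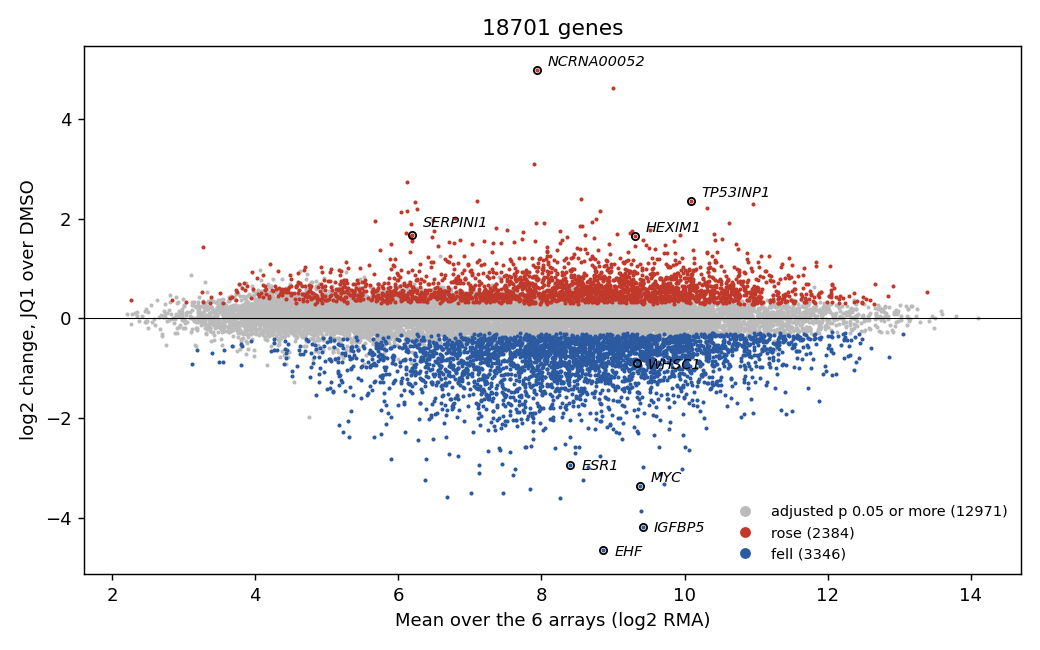
Log2 change with JQ1 (vertical axis) against the mean log2 signal over the 6 arrays (horizontal axis), with a point for each of 18701 genes. Genes that rose (2384) are red, genes that fell (3346) are blue and the others are grey.

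Of the estrogen receptor and luminal factors, 5 of 16 rose and 3 fell, with 8 not passing (7 rose and 3 fell when adjusted over the list alone). The falls were ESR1, the luminal transcription factor gene SPDEF (fell by 1.29) and XBP1. All 14 probe sets of ESR1 were lower with JQ1. The rises included TBX3 (log2 change 0.92) and TFAP2C (0.72), both genes of transcription factors active in luminal cells. FOXA1, a pioneer factor gene of estrogen receptor binding, had a log2 change of 0.13 (adjusted p = 0.318), and GATA3 one of 0.21 (adjusted p = 0.178). The list's median change was 0.22, its mean was -0.02 and its test pointed up without passing (adjusted p = 0.367).

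Estrogen-induced genes fell as a list (median log2 change -0.19, camera adjusted p = 0.00179; adjusted p = 0.144 with an estimated correlation). The list's call was lost among genes above the 50th percentile of signal. Of 35 measured members, 16 fell, 1 rose and 18 did not pass (17 fell and 2 rose when adjusted over the list alone). TFF1, a secreted peptide gene widely used as an estrogen marker, fell by 1.12 ± 0.15 (SE; adjusted p = 8.90e-04). CCND1, the cyclin D1 gene, fell by 0.60 ± 0.09 (SE; adjusted p = 0.00222). RAPGEFL1 fell by 1.26 and IGFBP4, an insulin-like growth factor binding protein gene, fell by 1.14, although the brightest IGFBP4 probe set alone gave 0.27 and did not pass. KRT19, a luminal keratin gene, rose by 1.06. GREB1, a cofactor gene of the estrogen receptor, was dim in both groups and had a log2 change of -0.06 (adjusted p = 0.720), with 41 probe sets between -1.24 and 1.34. It passed only with centring on housekeeping genes, at -0.42. PGR, the progesterone receptor gene, had a log2 change of 0.10 (adjusted p = 0.568). Estrogen-repressed genes went both ways, with 5 of 16 up and 3 down (6 and 3 when adjusted over the list alone), and the list did not pass (median 0.02, adjusted p = 0.784). TP53INP1, an autophagy and stress gene, rose by 2.36 and CCNG2, an unconventional cyclin gene, by 1.72 (0.96 with the mean of its probe sets), whereas BCAS1 fell by 1.51 and the transcription factor gene KLF4 fell by 1.13.

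SET domain methyltransferase genes, to which WHSC1 belongs, fell as a list (median log2 change -0.36, camera adjusted p = 0.00729; adjusted p = 0.639 with an estimated correlation). Of 19 members 10 fell, none rose and 9 did not pass (12 fell and 1 rose when adjusted over the list alone). The list's call was lost among genes above the 50th percentile of signal. SMYD2, a lysine methyltransferase gene, fell by 1.12, and 33 of the 34 probe sets of WHSC1 were lower. Its relatives NSD1 and WHSC1L1 fell by 0.51 and 0.36. EZH2, the Polycomb methyltransferase gene, fell by 0.52 (adjusted p = 0.0140).

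MYC target genes fell as a list (median log2 change -0.89, camera adjusted p = 8.89e-15; adjusted p = 0.144 with an estimated correlation). Of 32 members 30 fell and none rose (30 fell and 1 rose when adjusted over the list alone). TFAP4, a transcription factor gene directly activated by MYC, fell by 1.84, and MRTO4, a ribosome assembly gene, fell by 1.58. In the MYC family itself 4 of 10 members fell and 2 rose, the same counts as when adjusted over the list alone, and the list did not pass (median -0.03, adjusted p = 0.540). MYC fell by 3.34 ± 0.12 (SE), with all 7 probe sets lower, and MXD1, a gene of a MYC antagonist, fell by 0.78. MXD4, another antagonist gene, rose by 1.74. MYCL1 rose by 0.36 (adjusted p = 0.0450), a call that was lost without DMSO replicate 1 or 2 or without any JQ1 replicate (adjusted p between 0.0610 and 0.151).

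The DNA replication and E2F list had the lowest test p of the 32 lists (median log2 change -1.59, camera adjusted p = 1.40e-23; adjusted p = 0.144 with an estimated correlation). All 31 members fell, also when adjusted over the list alone, among them UHRF1, which maintains DNA methylation (5.01-fold lower), and the replicative helicase gene MCM7 (fell by 1.90). Mitosis genes followed, with 30 of 31 down and none up, the same counts as when adjusted over the list alone (median -1.15, camera adjusted p = 6.60e-18; adjusted p = 0.208 with an estimated correlation). The spindle midzone gene PRC1 fell by 1.68, but its brightest probe set alone gave 0.09 and did not pass. The mitotic kinase gene AURKB fell by 1.28. Of the homologous recombination and DNA repair genes 18 of 20 fell and none rose, again the same when adjusted over the list alone (median -1.34, camera adjusted p = 2.24e-12; adjusted p = 0.315 with an estimated correlation). EXO1, a resection nuclease gene, was 5.74-fold lower and the helicase gene BLM was 4.24-fold lower. Cyclins and CDK inhibitors of G1 did not pass as a list (median -0.07, adjusted p = 0.317), with 6 of 16 down and 2 up (6 and 3 when adjusted over the list alone). RBL1, a gene of a pocket protein related to the retinoblastoma protein, fell by 1.68, and CDK4 fell by 0.99. CDKN2D rose by 0.67, but not past the threshold with centring on housekeeping genes (0.31). CDKN2A rose by 0.49 (adjusted p = 0.0481), a call lost without any 1 of 5 arrays (adjusted p between 0.0861 and 0.147), and it moved to 0.05 with the mean of its probe sets. Its signal was dim, at 5.82 with DMSO and 6.31 with JQ1. CDKN1A, which encodes the cell cycle inhibitor p21, had a log2 change of 0.45 ± 0.15 (SE; adjusted p = 0.0553), and passed without DMSO replicate 3 (0.56) and with most other settings.

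Clustered histone genes fell as a list (median log2 change -0.82, camera adjusted p = 0.00269; adjusted p = 0.315 with an estimated correlation). Of 32 members 18 fell, 8 rose and 6 did not pass (19 and 8 when adjusted over the list alone). The list's call was lost with centring on housekeeping genes and among genes above the 50th percentile of signal (adjusted p = 0.255 and 0.312). The linker histone gene HIST1H1B fell by 2.75. The median of HIST2H2BE rose by 2.20, while its 4 probe sets changed by between -0.33 and 3.67 and the brightest by 3.66. The median of HIST1H2BE fell by 2.56, but it passed between probe sets of different level; its 5 probe sets changed by between -3.01 and 0.14, and it fell by 1.34 by their mean. The median of HIST1H2BD was 4.62 higher with JQ1, but it too passed between probe sets, from a dim probe set with DMSO to a bright probe set with JQ1 that itself fell by 0.61, so 4.62 is the change of no probe set. Its 5 probe sets changed by between -0.61 and 5.09, of which the brightest fell by 0.56. With each probe set centred before the median was taken, an alternative chosen after seeing the data, HIST1H2BD had a log2 change of 0.19 and did not pass.

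BET and P-TEFb genes, which cover the targets of JQ1 and the elongation kinase complex they recruit, had 4 of 10 members up and none down, also when adjusted over the list alone (median log2 change 0.08, adjusted p = 0.317). HEXIM1, an inhibitor of P-TEFb and a common marker of BET inhibition, rose by 1.66 ± 0.13 (SE; adjusted p = 8.46e-05), with 3 of its 4 probe sets higher and 0.93 by their mean. BRD2 rose by 0.81 ± 0.09 (SE; adjusted p = 5.30e-04), or 0.31 with its brightest probe set, and the kinase gene CDK9 rose as well. BRD3 rose by 0.40 ± 0.09 (SE; adjusted p = 0.0143), a call lost without DMSO replicate 1 (0.38), without DMSO replicate 2 (0.39), and with centring on housekeeping genes (0.05). BRD4 was not analysed here. Among 9 response markers of BET inhibitors 4 rose and 2 fell (5 and 2 when adjusted over the list alone), with no call for the list (median 0.34, adjusted p = 0.317) except with centring on housekeeping genes, where it passed at a median of -0.01. SERPINI1, the neuroserpin gene, rose by 1.68 ± 0.13 (SE; adjusted p = 8.6e-05) from a dim DMSO signal of 5.36. The falls were MYC and ZMYND8, a gene of a chromatin reader, which was 4.90-fold lower.

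**Figure D3:**
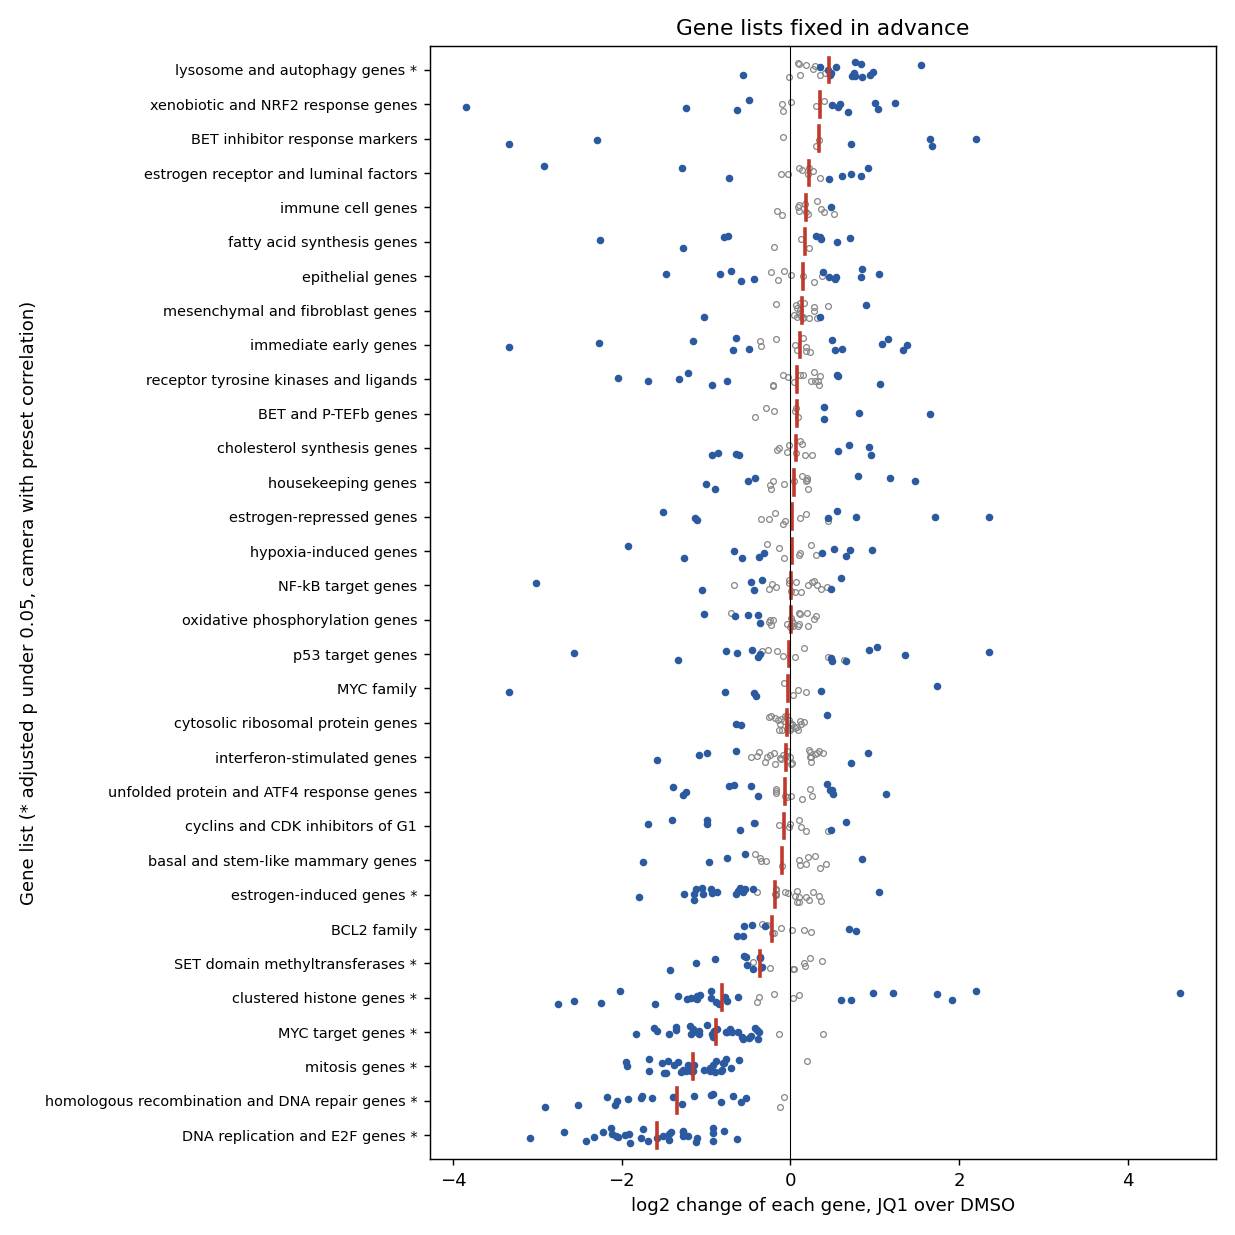
Log2 change with JQ1 (horizontal axis) of every measured member of the 32 gene lists (vertical axis), sorted by the list median (red bar). Filled points passed an adjusted p under 0.05 over all genes and an asterisk marks the 8 lists that passed camera, with medians from -1.59 for DNA replication to 0.46 for lysosome and autophagy genes.

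Lysosome and autophagy genes formed the only list that passed upwards (median log2 change 0.46, camera adjusted p = 3.73e-06; adjusted p = 0.144 with an estimated correlation). Adjusted over the list alone, 16 rose and 1 fell. The sialidase gene NEU1 rose by 1.55 and MCOLN1, which encodes a lysosomal ion channel, by 0.84. TFEB, a gene of a transcription factor that drives lysosome genes, fell by 0.56 (adjusted p = 0.0162), a call that was lost without DMSO replicate 1 (-0.55), and it had a change of 0.00055 with bright probe sets only. Cholesterol synthesis genes split evenly, with 4 of 17 up and 4 down, also when adjusted over the list alone (median 0.07, adjusted p = 0.784). INSIG1 and LSS rose by 0.93 and 0.96, and the sterol enzyme genes CYP51A1 and FDPS fell by 0.86 and 0.64 respectively. For fatty acid synthesis the median was 0.17, the mean was -0.22 and the test pointed down without passing (adjusted p = 0.896). There 5 of 12 rose and 4 fell, also when adjusted over the list alone. The lipogenic factor gene SREBF1 rose by 0.70, the elongase gene ELOVL6 fell by 2.26 and the desaturase gene FADS1 fell by 1.27. FASN, the fatty acid synthase gene, rose by 0.55, although its brightest probe set (0.08) and centring on housekeeping genes (0.19) ended that call.

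Targets of p53 went both ways, with 7 of 22 up and 7 down (8 and 8 when adjusted over the list alone), a median of -0.01, a mean of 0.06 and a test that pointed up without passing (adjusted p = 0.784). TP53INP1 and TP53I3, a redox enzyme gene, rose by 2.36 and 1.36. The stress cytokine gene GDF15 fell by 2.57 and the death receptor gene FAS fell by 1.33, the latter with 0.13 in its brightest probe set. FAS was dim, at 5.84 with DMSO and 4.51 with JQ1. In the BCL2 family 5 of 15 fell and 2 rose (6 and 2 when adjusted over the list alone; median -0.22, adjusted p = 0.403). The proapoptotic genes BAX and BID fell by 0.63 and 0.55. BID lost its call without JQ1 replicate 3 (-0.50), and the brightest BAX probe set gave 0.17. BMF, also proapoptotic, rose by 0.78, and the survival gene MCL1 rose by 0.69, but not past the threshold with centring on housekeeping genes (0.34). BCL2 itself had a log2 change of -0.34 ± 0.18 (SE; adjusted p = 0.188), which passed without JQ1 replicate 1 (-0.51) and with centring on housekeeping genes (-0.69), and turned to 0.40, past the threshold, with its brightest probe set.

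Interferon-stimulated genes mostly did not pass, with 2 of 31 up and 4 down, also when adjusted over the list alone (median -0.05, adjusted p = 0.784). The antiviral genes IFITM3 and IFITM2 fell by 1.58 and 1.09 respectively, and STAT2 and IRF1, transcription factor genes of that response, rose by 0.92 and 0.72. IRF1 lost its call with its brightest probe set (0.31). Among NF-kB targets 5 of 23 fell and 2 rose, also when adjusted over the list alone, with a median of 0.01, a mean of -0.15 and a test that pointed down without passing (adjusted p = 0.653). The chemokine gene IL8 was 8.12-fold lower, and BCL3 fell by 1.05. SOD2 rose by 0.48 but lost its call without DMSO replicate 1 or 3 or JQ1 replicate 2 (adjusted p between 0.0567 and 0.0737). CXCL2 rose by 0.60 but lost its call without DMSO replicate 2 or 3 or JQ1 replicate 1 or 3 (adjusted p between 0.0610 and 0.113). It was dim too, at 5.19 with DMSO and 5.79 with JQ1. Immediate early genes had 7 of 22 up and 6 down, also when adjusted over the list alone, with a median of 0.11, a mean of -0.09 and a test that pointed up (adjusted p = 0.784). FOS and JUN rose by 1.38 and 1.33, whereas SPRY4, a feedback inhibitor gene of receptor signalling, fell by 2.27. Of the unfolded protein and ATF4 response genes 7 of 21 fell and 5 rose, also when adjusted over the list alone (median -0.07, adjusted p = 0.540). TRIB3 fell by 1.39 (-0.71 with the mean of its probe sets), SDF2L1 fell by 1.28 and the asparagine synthetase gene ASNS rose by 1.13. ATF4 rose by 0.48, but its brightest probe set gave -0.19.

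The xenobiotic and NRF2 response list had 7 of 16 up and 4 down (8 and 4 when adjusted over the list alone), with a median of 0.35, a mean of -0.0045 and a test that pointed up without passing (adjusted p = 0.375). The redox genes TXNRD1 and SRXN1 rose by 1.25 and 1.0. AKR1C2, a steroid-reducing enzyme gene with close paralogs, was 14.4-fold lower by the median of its 5 probe sets, which spread from -3.96 to 1.62, and fell by 1.83 on the log2 scale by their mean. The cystine transporter gene SLC7A11 fell by 1.24. TXNRD1 moved to 0.32 with its brightest probe set. Hypoxia-induced genes had 5 of 18 up and 6 down (6 and 6 when adjusted over the list alone), with a median of 0.02, a mean of -0.09 and a test that pointed down (adjusted p = 0.784). The collagen cross-linking gene LOX fell by 1.93 and PDK1 fell by 1.26, whereas KDM3A rose by 0.97 and BNIP3L by 0.66. BNIP3L did not pass with centring on housekeeping genes (0.31). Receptor tyrosine kinases and ligands had 6 of 22 down and 3 up (6 and 6 when adjusted over the list alone), with a median of 0.08, a mean of -0.19 and a test that pointed down (adjusted p = 0.787). The RET coreceptor gene GFRA1 fell by 2.04 and MET fell by 1.69, whereas the receptor genes FGFR1 and FGFR3 rose by 1.07 and 0.57. FGFR3 did not pass with centring on housekeeping genes (0.21).

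Epithelial genes had 7 of 19 up and 5 down (8 and 5 when adjusted over the list alone; median 0.15, adjusted p = 0.653). The desmosome gene DSP rose by 0.85, the keratin gene KRT80 fell by 1.47 and the tight junction gene CLDN7 fell by 0.83. Mesenchymal and fibroblast genes had 2 of 20 up and 1 down (1 and 1 when adjusted over the list alone; median 0.13, adjusted p = 0.344). SNAI2 rose by 0.90 and the fibronectin gene FN1 fell by 1.03. VIM, the vimentin gene, rose by 0.35 (adjusted p = 0.0454), a call lost on leaving out any array (adjusted p between 0.0519 and 0.117), and it turned to -0.0024 with centring on housekeeping genes. Basal and stem-like mammary genes had 4 of 17 down and 1 up, also when adjusted over the list alone (median -0.10, adjusted p = 0.540). CD44, a surface glycoprotein gene, fell by 0.97 and SOX2 rose by 0.85. ALDH1A3 fell by 1.75, but its brightest probe set gave 0.39. Immune cell genes were dim (median log2 signal 5.57), and 1 of 13 rose, or none when adjusted over the list alone (median 0.19, adjusted p = 0.317). That gene was CD4 (log2 change 0.49), whose call was lost without DMSO replicate 1 or 2 or JQ1 replicate 2 (adjusted p between 0.0524 and 0.0935).

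Cytosolic ribosomal protein genes had 2 of 28 down and 1 up, also when adjusted over the list alone (median -0.04, adjusted p = 0.626). RPL37 fell by 0.64. RPL32 fell by 0.59, but its brightest probe set gave 0.02. RPL14 rose by 0.44, but lost its call without DMSO replicate 1 or JQ1 replicate 1 or 3 (adjusted p between 0.0537 and 0.0707) and turned to -0.11 with its brightest probe set. Of the oxidative phosphorylation genes 5 of 25 fell and none rose, also when adjusted over the list alone, with a median of 0.01, a mean of -0.12 and a test that pointed down without passing (adjusted p = 0.486), except with the brightest probe set of each gene, where it passed at a median of -0.06. The complex I genes NDUFA9 and NDUFS1 fell by 1.03 and 0.65 respectively. Housekeeping genes had 3 of 17 up and 4 down, also when adjusted over the list alone (median 0.04, adjusted p = 0.896). B2M rose by 1.48 and POLR2A, the largest subunit gene of RNA polymerase II, by 1.18, whereas HPRT1 fell by 1.0 and IPO8 fell by 0.89. The brightest B2M probe set alone gave 0.0048.

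By the rule fixed for the largest rises, the noncoding RNA gene NCRNA00052 came first, with a log2 change of 4.97 from a DMSO signal of 5.45. HIST1H2BD came next by the change of its median alone, since the probe sets of HIST1H2BD moved apart and gave 0.19, not past the threshold, when centred. ROPN1L (3.09) and TEX14 (2.72) followed. The DMSO signals of NCRNA00052, TEX14, MAP2 and KIAA1324L, and the JQ1 signals of TSPAN8, RASGRP1 and FAR2 among the falls, were under 5.74, the 25th percentile of gene means. Background was not measured, so the true folds of these genes are not known. Also among the 12 were the stress genes SESN3 (log2 change 2.38) and TP53INP1 (2.36), the neuronal cytoskeleton genes DPYSL3 (2.35) and MAP2 (2.33), the imprinted gene PEG10 (2.29), HIST2H2BE (2.20), KIAA1324L (2.19) and the epoxide hydrolase gene EPHX1 (2.14). With the brightest probe set of each gene, TEX14 moved to 1.65, PEG10 to 0.90 and KIAA1324L to 0.60. The largest fall was in EHF, an epithelial transcription factor gene, at 24.9-fold lower, followed by IGFBP5, an insulin-like growth factor binding protein gene, at 18.0-fold and AKR1C2 at 14.4-fold, or -1.83 by the mean of its probe sets. WDR76 (-2.38 with its brightest probe set), TSPAN8 and RASGRP1 fell by 3.59, 3.57 and 3.5 on the log2 scale, the last with -0.11 in its brightest probe set. HIST1H2AL fell by 3.41 and had a change of -0.39, not past the threshold, with each probe set centred before the median. MYC, SLITRK6, FAR2, DTL and CP, the ceruloplasmin gene, completed the 12 falls, the last at -3.14.

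Probe sets of a gene were called as responding unequally in 3306 of 10711 genes tested for exon usage (30.9%, with 4152 at an unadjusted p under 0.05). Of the called genes 1208 were not called as whole genes. In simulated data 62 unchanged genes made up a large share of the calls of this test. An unknown part of the 3306 may therefore be false. Among genes changed by under 0.2 on the log2 scale 700 of 3621 (19.3%) were called, against 694 of 993 (69.9%) among genes changed by at least 1. With probe sets above the 75th percentile of signal only, 1371 genes were called. The lowest p belonged to FN1 (adjusted p = 4.62e-44), whose 55 probe sets changed by between -2.31 and -0.47. The brightest of them, at a mean signal of 13.66, changed by -0.67, and the dimmest, at 8.66, by -1.46. Whether very bright probe sets understated their change was not tested. Next came MSI1, an RNA-binding protein gene, with 14 probe sets between -3.25 and 0.42, and TENC1, with 25 between -3.21 and -0.01. SLC3A2, which encodes a subunit of amino acid transporters, had a log2 change of -0.10 as a whole gene (adjusted p = 0.523), while its 15 probe sets spread from -1.58 to 0.69. ESPL1, the separase gene, had 26 probe sets between -2.86 and 0.55.

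Genes were tested with limma and lists with camera at a preset correlation between genes of 0.01; 8 lists passed, 7 lower and 1 higher, and none did with an estimated correlation. The rotation test fry, which asks whether the genes of a list move on balance one way and compares them with no other genes, passed 21 lists, and its mixed form, which asks for change in either direction, passed all 32. Equal masses of RNA were labelled and arrays were scaled to each other, so the values are relative within each array and do not show whether total RNA per cell changed.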

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

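Probe sets outside the gene tests also carried a response to JQ1, which is why they are given here. The tests of these probe sets were chosen after the data were seen. Of 22951 probe sets with no gene listed, 1965 (8.56%) changed at an adjusted p under 0.05, of which 927 rose and 1038 fell. Of 10159 probe sets with several gene symbols, 1512 (14.9%) changed, of which 544 rose and 968 fell. Among probe sets with 1 symbol 18.8% changed. The difference between these shares was not tested.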

How the results depend on the processing

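The median of row-centred values was chosen after the data were seen; the other alternatives were set before. ESR1, WHSC1, MYC, HEXIM1, BRD2, TFF1, CCND1 and SERPINI1 kept their direction and side of the threshold under every alternative that tested them. Over all named genes, 2268 comparisons kept their call, 86 lost the threshold (26 genes), 15 gained it and 18 turned direction (13 genes). For lists, 644 kept their call, 12 lost the threshold (8 lists) and 15 gained it. Genes and lists that passed in neither setting were counted as keeping their call, whatever their direction. Turns of direction among them were not counted. Of the list comparisons, 8 of the losses came from camera with an estimated correlation and 13 of the gains from fry. Of the 5730 changed genes, 5190 were also called with the mean of a gene's probe sets and 3750 with its brightest probe set, 3614 of these in the same direction. The percent of falls among 1.5-fold changes, 69.1, moved to 58.8 with the brightest probe set, 59.0 with quantile normalization, 94.2 with centring on housekeeping genes and 53.1 with centring on all genes. Centring on housekeeping genes gave 608 rises and 7079 falls, and at 1.5-fold 287 and 4676, because it shifted all genes down together. The median level it subtracted can pass between genes, and the 17 genes themselves had a median log2 change of 0.04. Centring on all genes gave 3973 rises and 2778 falls, and at 1.5-fold 1612 and 1828. Rises also outnumbered falls with quantile normalization (3189 and 3010), the brightest probe set (3046 and 2770) and the median of bright probe sets (3492 and 3352). The stricter adjusted p under 0.01 left 3444 genes, 1167 of them rises, and treat left 2792 (835 rises, 1957 falls). Row-centred values gave 3656 rises among 7672 changed genes, 5226 of them shared with the 5730. The count of 8 lists became 5 among genes above the 50th percentile, 0 with an estimated correlation and 21 with fry, which asks another question. Exon usage fell from 3306 genes to 1371 with probe sets above the 75th percentile, where fewer genes could be tested. Leaving out an array gave 4319 to 5602 changed genes, 8 lists each time, 2317 to 3927 genes in exon usage and 66.4 to 69.8 percent falls.

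The values counted as turned in direction were, with the brightest probe set, 0.40 for BCL2, -0.56 for HIST1H2BD, 0.27 for IGFBP4, 0.086 for PRC1, 0.13 for FAS, 0.17 for BAX, -0.19 for ATF4, -0.068 for VIM, 0.39 for ALDH1A3, -0.12 for CD4, -0.11 for RPL14 and 0.016 for RPL32. They were -0.21 for HIST1H2BD and 0.00055 for TFEB with bright probe sets only, -0.0024 for VIM with centring on housekeeping genes, -0.088 for RPL14 with the mean of probe sets, and -0.043 for ATF4 and -0.11 for RPL14 with row-centred values. For these and for the moved counts without a stated reason, the cause was not tested. Signal close to background limits dim genes: of the 4676 dimmest genes, 241 rose and 154 fell.

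With the replicate number as a block, 5761 genes changed (5304 shared), 8 lists passed and 3821 genes were called in exon usage, and no named gene changed its call. Arrays with the same number deviated together at r = 0.092, -0.012 and 0.247 across genes, against -0.225 to 0.161 for different numbers, and 3 of the 6 arrays correlated best with their own number, so the numbers were not taken to pair the arrays.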

Other observations

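Families sharing a symbol prefix were tested after the data were seen, as were the histone, single-direction and 4-fold tests, the opposite probe sets, and the recounts with all probe sets and among the brightest genes after centring; the splits and the other exon usage and 1.5-fold tests were set before. With limma's camera, 17 of 254 families of at least 10 genes passed, 13 lower and 4 higher, and none did with an estimated correlation (adjusted p = 0.968 for each). Mitochondrial ribosome genes fell, with 24 of 47 MRPL genes down and 1 up (median log2 change -0.36, adjusted p = 1.76e-05) and 14 of 29 MRPS genes down and 1 up (-0.35, adjusted p = 0.00112). Nuclear pore genes (NUP) had 13 of 21 down and 1 up (median -0.72), RNA exosome genes (EXOSC) 7 of 10 down and 1 up (-0.66) and mitochondrial import genes (TIMM) 7 of 11 down (-0.65). Protocadherin beta genes (PCDHB), dim at a median signal of 5.36, had 9 of 18 down (-0.50). Of the other clustered protocadherins, PCDHA had 2 of 13 down (camera adjusted p = 0.503). PCDHGA had 1 of 12 down and 3 up (camera adjusted p = 0.746), and neither family passed.

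The higher families were exocyst genes (EXOC), with 5 of 11 up (median 0.34), collagen genes (COL), with 5 of 44 up (0.21), small nuclear RNA genes (RNU), with 6 of 14 up and 1 down (0.38), and olfactory receptor genes (OR), with 12 of 370 up (0.12) at a median signal of 4.66. Over all genes 2384 of 18701 rose, and among the 4676 dimmest genes 241 rose, with a median change of 0.096. The shares of COL and OR genes that rose were below that of all genes. That of OR was also below that of the dimmest genes, whose median change was close to its own. The medians of the higher families stayed above 0 with quantile, cyclic loess and all-gene scaling. Centring on housekeeping genes, which moved the median of all genes from 0.06 to -0.30, turned those of EXOC, COL and OR to -0.0096, -0.14 and -0.23. The 17 housekeeping genes themselves had a median change of 0.04, so that shift is larger than their own change. The NUP, EXOSC, TIMM, MRPL, MRPS and PCDHB medians lay between -0.65 and -0.25 with quantile scaling and between -0.62 and -0.25 with all-gene centring, which moves genes up.

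Histone genes held probe sets that moved apart. Of 58 clustered histone genes with at least 2 probe sets, 12 had both a rising and a falling probe set. In 10000 random draws of other genes with as many probe sets, the median was 0 and the highest count 3. The draws were not matched on how often probe sets changed. Of 186 histone probe sets 22 rose and 101 fell, whereas 18.8% of all probe sets with 1 symbol changed. The draws therefore cannot tell whether chance mixing of such frequent changes gave the 12. Unequal response of probe sets to a change of the whole gene in 1 direction is argued against, since in 9 of 31 genes of the histone list the probe sets rejected a common direction (adjusted over the list), as in HIST1H2BC, with changes from -1.59 to 3.98. Sharing of probes between near-identical gene copies stays open, since the falling probe sets of mixed genes fell less than those of other histone genes by 0.431 (permutation p = 0.0955). No biological explanation was tested.

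Among 1.5-fold changes falls outnumbered rises as deposited. Scaling of the arrays by the authors stays open for the 1.5-fold changes, since centring on all genes brought falls to 53.1%. Under that centring falls made up 70.6% of 2-fold changes (344 rose, 828 fell) and 78.8% of 4-fold changes (22 rose, 82 fell). That centring pushed all genes up, from a median change of 0.06 to 0.16, a small shift beside a 4-fold change. Its 4-fold result therefore decides nothing, and scaling stays open there too. Unequal visibility of changes in dim genes stays open too: falls made up 63.5% of 1.5-fold changes among the 4675 brightest genes, past the bound set to argue against it, but that bound assumed the deposited scaling, and the share was 47.4% (599 rose, 539 fell) after centring on all genes. No biological explanation beyond JQ1 itself was tested.

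Unequal probe response within genes was weighed for exon usage. Probe sets may respond unequally to an equal change of the whole gene: the share of genes called among those changed by under 0.2 was 0.277 of the share among those changed by at least 1, between the bounds set for either reading, so this cannot be told apart from altered transcripts. Compression of change in dim probe sets stays open. Among called genes, where only bright probe sets were used, the dimmest probe sets changed 1.35 times as much as the brightest. That ratio leaves out dim probe sets. Over all 16742 probe sets of 1188 genes changed 2-fold, the ratio was 0.991 for changes in the direction of the gene. There the median change was 1.188 in the dimmest probe sets, 1.350 in those of middle signal and 1.199 in the brightest. The dimmest thus changed less than those of middle signal, and a comparison with the brightest alone cannot decide. Compression in the brightest probe sets was not tested. Among called genes their median size of change was 0.428, against 0.580 in the dimmest. Over all 10711 genes, none rejected a common direction of its probe sets with limma p-values adjusted over genes (0 genes; 228 at an unadjusted p under 0.05), which decides nothing for genes outside the histone list. Among the 111247 probe sets above the median signal used for exon usage, a probe set that rose and another that fell, each 2-fold at an adjusted p under 0.01, were found in 6 genes (ABCC4, GABPB2, HIST1H2BC, HIST1H2BF, TOMM40L and TTC12), all 6 of them called for exon usage.

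The 6 arrays make 10 splits into 3 and 3, too few for a share under 0.05. The real split called 5730 genes against at most 0 in the others, 8 lists against 3 to 7 and 3306 genes in exon usage against at most 106. In each case 1 split, the real one, reached its own value. Every other split mixed DMSO and JQ1 arrays within its groups, so the spread within its groups holds the effect of JQ1.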
